A study of Mus musculus with 8 samples.

How the data were processed

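The series is a low-input CUT&RUN experiment on mouse primordial germ cells (PGCs), the embryonic precursors of eggs and sperm. In CUT&RUN an antibody directs a protein A-micrococcal nuclease fusion to its target in intact nuclei, and the released DNA fragments are sequenced. The antibodies were against H3K27me3, the histone mark placed by Polycomb repressive complex 2, and IgG, which gives the background of untargeted cleavage. Per the labels, the cells were sorted from pooled embryos of 1 sex. The animals were B6 x Cast hybrids, females were heterozygous for an Xist knockout and males carried the knockout on their only X. Xist is the long non-coding RNA that coats and silences the X chromosome from which it is transcribed.

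The labels list 8 samples, and 5 of them had a processed file that was used, with 1 library in each group: H3K27me3 from females at E11.5 and at E12.5, and IgG from males at E11.5 and from females at E12.5 and at E13.5. The other 3 samples are labelled as second replicates of the H3K27me3 groups (2 parts at E11.5 and 1 sample at E12.5). They had no file here and were not analysed. No group had a second library with a file, so no spread between replicates could be measured, no p-value between conditions is given, and no replicate could be left out.

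Each deposited file gives, per gene, whole-number counts of reads on 2 alleles and the fraction of those reads that lie on the second allele. The authors' fraction equals the second count divided by the sum of both in every gene with reads (largest difference below 1e-12), and is printed here as a percent and called the second-allele share. The deposited counts are not normalised, and their totals differ between libraries. Per the submitters' processing notes, the tools were FastQC 0.11.9, MultiQC 1.13, cutadapt 4.1, Trim Galore 0.6.6, Bowtie2 2.4.2, SAMtools 1.11, GATK, deepTools 3.5.1, MACS2 2.2.7.1 and featureCounts, and the genome build was mm10. Their roles and order, the treatment of duplicate reads and the way reads were assigned to an allele are not given in the sources used here. Reads without a variant between both strains carry no allele information, so the counts hold an unknown part of each library. Which strain is the first and which the second allele is not stated either, and the alleles are named by their order.

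The files hold 21352 genes, of which 885 are on the X, 20368 on autosomes and 94 on the Y, and 5 are listed at a pair of positions. Coordinates were taken from a RefSeq gene table of GRCm38.p6, the assembly that mm10 names, for 21170 genes (21087 matched by symbol and 83 by synonym). Genes on the Y and genes listed at a pair of positions were left out of all comparisons. They took between 0.0692% and 0.112% of the reads of a library.

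The share measures, their tests, the gene lists, thresholds and the rule for naming genes were fixed before the data were examined. Read levels, reads per allele relative to autosomal reads, the comparisons with IgG E13.5 and the summaries of genes one-sided in IgG were added after seeing the data. A gene entered a library's summary with at least 10 allelic reads there. The median second-allele share over X genes was set beside 10000 random sets of as many autosomal genes of the same library, matched on coverage. Pooled shares carry exact Clopper-Pearson 95% intervals. Genes at least 20 points from 50% were counted per library. An exact two-sided binomial test per gene was run against the library's pooled autosomal share, and Fisher's exact test (two-sided) per gene compared the libraries of both stages, and H3K27me3 with IgG at E12.5. All p-values were adjusted by Benjamini-Hochberg over the X and autosomal genes tested, with a threshold of 0.05. These tests compare these libraries, not the conditions. PCR duplicates may remain among the reads, so intervals and tests cover counting error only.

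There were 14 gene lists. Those on the X were escape genes, genes around the X inactivation centre, germline genes, housekeeping genes, and neural or developmental genes. The autosomal lists were canonical imprinted genes, genes with H3K27me3 imprints in oocytes, Hox genes, developmental regulators, germline genes, pluripotency genes, somatic gonad markers, blood and endothelial markers, and housekeeping genes. A list's median share was set beside 10000 random sets of as many genes of the same class. Read levels per gene were reads of both alleles scaled to the library's autosomal reads (counts per 10 to the power of 6). Level ratios were taken on the log2 scale with a pseudocount of 1 on that scale, over genes with at least 20 reads in the pair of libraries together, which understates ratios of sparsely covered genes. The levels of single alleles were taken over X genes with at least 10 reads in both H3K27me3 libraries, at least 20 in IgG E13.5 and an IgG E13.5 share within 20 points of 50%. The named genes were, among the 485 X genes with at least 20 reads in both H3K27me3 libraries, the 5 highest and 5 lowest shares at each stage and the 5 largest rises and falls. All X members of the X lists, and autosomal list members past the 20-point threshold on the same side in both H3K27me3 libraries, were added. Some of these genes are not reported here.

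Alternatives covered the mean and the pooled share in place of the median, minimums of 5 and 20 reads, and the X without 1 Mb on each side of Xist and without the pseudoautosomal end. Further alternatives were shares relative to IgG E12.5 or to the library's autosomal median, genes with a value in all 5 libraries, thresholds of 10 and 30 points, and 1 Mb bins. A version of the lists by the window at the transcription start does not apply, because the values are per gene. The tests were checked on simulated counts at the real depths, with 200 genes shifted from 50%. Of the genes shifted by 20 points, the binomial test at E12.5 recovered 55.5% (95.8% of those with at least 100 reads, from the same 17803 genes), and the Fisher test between stages recovered 34% among 15877 genes. A shift of 10 points was recovered in 19.5% and 5% of the genes. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.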

Results

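Allele-resolved CUT&RUN reads were collected from sorted PGCs of B6 x Cast hybrid embryos, in 5 libraries that each stood for 1 group. The H3K27me3 libraries came from Xist-heterozygous females at E11.5 and E12.5 and held 2451205 and 5250167 allele-assigned reads. IgG libraries came from Xist-knockout males at E11.5 (1378513 reads) and from heterozygous females at E12.5 (1547793 reads) and E13.5 (5880641 reads). The X chromosome took 92099 and 224639 reads in the H3K27me3 libraries, and 19952, 31149 and 171170 in the IgG libraries in the same order. X genes had a median of 61 and 112 reads at E11.5 and E12.5. The second replicates that the labels list for both H3K27me3 groups had no file here, so with 1 library per group there was no replicate check, and every interval covers counting error only. The question the design poses is how H3K27me3 is divided between both X chromosomes of female PGCs across these stages.

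In IgG, both X chromosomes of females contributed nearly equal reads, and the single X of males was read almost entirely as the first allele. The female pooled X share of the second allele was 48.7% at E12.5 (95% interval 48.1 to 49.3) and 49.5% at E13.5 (49.2 to 49.7). The per-gene medians were 47.5% over 453 X genes and 49.0% over 628, against autosomal medians of 50% and 50.2%. Both X medians lay below the lowest of 10000 random autosomal sets of matched coverage (48.6% and 49.5%), a slight tilt toward the first allele. In the male library the pooled X share was 6.30% (5.96 to 6.64) and the median over 339 genes was 3.70% (interquartile range 0 to 6.90%), while autosomes stood at 50.8%. Mid1, a microtubule-associated ubiquitin ligase gene that crosses the pseudoautosomal boundary in laboratory mice, supplied 197 of the 1256 male second-allele reads and had a share of 58.5%. Without it the male X share was 5.40%. By the 20-point threshold, 332 of the 339 male X genes lay on the first-allele side and 1, Btk, on the other, with 10 of 10 reads.

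Certain X genes were one-sided in the IgG libraries too. In the E13.5 female library, 21 X genes had at least 80% of reads on the second allele, among them Dgkk, encoding a diacylglycerol kinase (98.3% of 298 reads), Btk, the kinase of B cell receptor signalling (100% of 88 reads), and Gla, the lysosomal alpha-galactosidase (100% of 23 reads). These 3 examples were chosen after their values were seen. In the male library, whose other X genes were at 6.10%, the 21 genes together had 41.8% of 110 reads on the second allele (32.5 to 51.6).

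**Figure D1:**
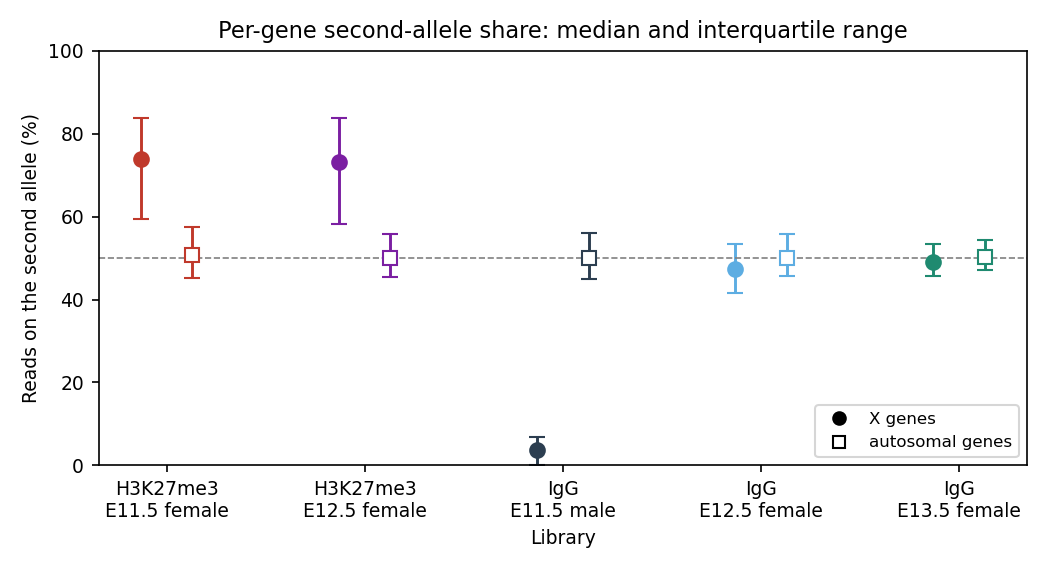
Per-gene percent of allelic reads on the second allele in each of the 5 libraries, as the median (circle for X genes, square for autosomal genes) with the interquartile range (bars). The X medians are 73.9% and 73.2% in the H3K27me3 libraries, 3.70% in the male IgG library and 47.5% and 49.0% in the female IgG libraries, and the autosomal medians lie between 50% and 50.8%.

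In the E11.5 H3K27me3 library, most X genes had more reads on the second allele. Gpc3, a cell-surface glypican, stood at 85.5% (83.1 to 87.7 by exact interval), Shroom4, an actin-binding gene, at 81.7%, and Chic1, next to Xist, at 87.0%. Atrx, a chromatin remodeller, had 84.8% and Hprt, a purine salvage enzyme gene, 85.9%. The median over 582 X genes was 73.9% (interquartile range 59.5 to 83.7), and 501 genes lay above 50% and 73 below. The autosomal median was 50.8%, and the highest of 10000 random autosomal sets of matched coverage was 52.6%. The pooled X share was 69.4% (69.1 to 69.7), against 51.6% on autosomes.

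By the 20-point threshold, 325 X genes lay on the second-allele side and 7 on the first. The exact binomial test with Benjamini-Hochberg adjustment called 309 genes toward the second allele and 13 toward the first, and it called 12.1% of autosomal genes as well. Of the 5 highest X genes, Dgkk, Rps6ka6, Vsig1 and Tmem35a were at 100% here and at 98.3% or more in IgG E13.5. Nudt11, an inositol phosphate hydrolase gene, had 23 of 23 reads on the second allele and 50% in that IgG library. The 5 lowest were Magea2 (20.7%), Pbsn (26.7%), Magea6 (28.6%), 6030498E09Rik (29.0%) and Ssxb2 (29.2%). Magea and Ssxb genes belong to families of near-identical copies, so the reads behind them are uncertain.

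At E12.5 the mark was divided in nearly the same way. The median over 654 X genes was 73.2% (58.3 to 83.7), with 566 above 50% and 80 below, the autosomal median was 50%, and the highest random autosomal set was 51.5%. The pooled X share was 71.0% (70.8 to 71.2). Gpc3 stood at 88.7%, Chic1 at 88.8%, Shroom4 at 85.3% and Tex11, a meiotic recombination gene, at 80.6%. The threshold placed 366 genes on the second-allele side and 13 on the first, and the binomial test called 409 and 23, and 17.9% of autosomal genes. Of the genes called toward the second allele, 298 were called at both stages.

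On the first-allele side, 7 X genes were called by the binomial test at both stages, and they were singled out after their values were seen. They were Tbx22, a palate and tongue developmental regulator (32.2% at E11.5 and 22.7% at E12.5), Pcdh11x, a protocadherin (36.5% and 32.4%), Prps1, a nucleotide synthesis gene (37.3% and 44.6%), Pbsn, Tent5d, Prame and Magea2. In IgG E13.5 their shares ran from 36.2% for Tbx22 to 60% for Prame. The 5 lowest at E12.5 were Tbx22, Magea2 (23.0%), Magea6 (26.6%), Pbsn (28.4%) and Gm15128 (30.1%). The highest were Atg4a, Vsig1 and Tmem35a at 100%, Ccnb3 and Dgkk at 99.7%, all of them above 98% in IgG E13.5.

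**Figure D2:**
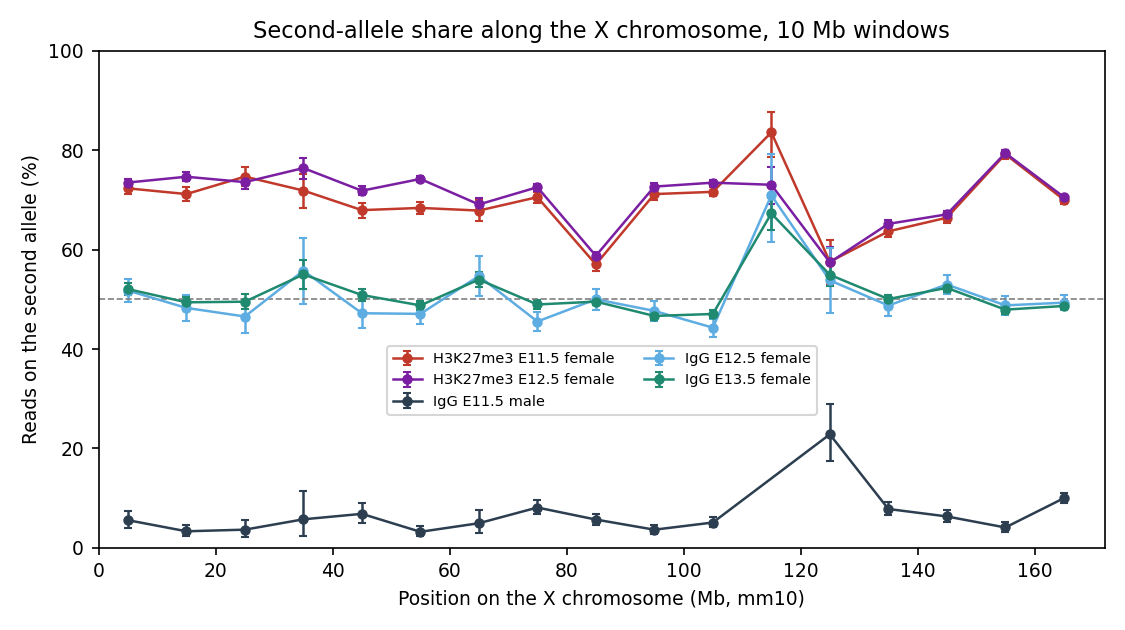
Percent of allelic X reads on the second allele in 10 Mb windows along the X (mm10) for the 5 libraries, with exact 95% counting intervals, in windows with at least 100 reads. The H3K27me3 values are lowest from 80 to 90 Mb (57.0% and 58.8%) and from 120 to 130 Mb (57.6% and 57.4%), the latter with intervals that overlap those of IgG, and the male library lies at 22.8% or below in the windows drawn.

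The second-allele share differed between windows of the X. In the window from 80 to 90 Mb, which holds Dmd and Il1rapl1, the share was 57.0% at E11.5 (55.8 to 58.3) and 58.8% at E12.5 (58.0 to 59.5). Dmd supplied 3493 and 8740 of this window's 6057 and 15019 reads, and Il1rapl1 1906 and 4639. These genes set most of the window's value, which does not describe the region as a whole. From 150 to 160 Mb the share was 79.2% and 79.4%. The female IgG libraries had 50% and 49.5% in the first of these windows and 48.8% and 47.9% in the second.

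Between E11.5 and E12.5 the second-allele share on the X differed little, in a direction that depended on the measure. Fgf13, a growth-factor homologue that binds sodium channels in neurons, rose from 51.5% to 60.9% (Fisher's exact test, adjusted p = 9.93e-06), and Nhs, mutated in a syndrome of cataract and dental anomalies, rose from 67.3% to 74.9% (adjusted p = 0.00034). Bcorl1, a transcriptional corepressor gene, rose from 76.1% to 86.8%, Gpc4 from 57.6% to 68.2%, Iqsec2, a synaptic exchange factor gene, from 77.4% to 86.0%, and Elf4, a transcription factor gene, from 43.8% to 52.6%. These 6 were all the X genes that the Fisher test called between both libraries, none fell, and 63 had an unadjusted p under 0.05. They are named because they were called, which was known only after their values were seen.

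The median change over 580 X genes was +1.05 points (interquartile range -3.71 to 5.22), with 327 genes higher at E12.5 and 248 lower, while the median share over the same genes went the other way, from 73.9% to 73.6%. On autosomes it was -0.47 over 15297 genes, and 1 of 10000 random autosomal sets of matched coverage lay as high as the X. The female IgG libraries, without the mark, differed by more, with a median of +1.56 points from E12.5 to E13.5 over 453 X genes, against 0 on autosomes. The pooled X share was 1.57 points higher (Fisher's exact test on pooled reads, p = 1.93e-18), a comparison of these libraries and not of the stages. Across X genes the shares at both stages had a Spearman correlation of 0.829, over genes that are not independent replicates. The size of the change depended on the setting: its mean over genes was 0.375 points and the median over 1 Mb bins 0.191. The libraries also differed on autosomes, where the Fisher test called 23 genes higher and 59 lower at E12.5, 32 of these 82 on chromosome 17.

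The largest shifts by size lay in sparsely read genes and none passed the adjusted test. Ssxb2 went from 29.2% to 71.4% (24 and 49 reads, adjusted p = 0.126 by Fisher's exact test) and Pnck, a calcium-dependent kinase gene, from 51.6% to 75%. Hccs, Tmem29 and Bmp15, an oocyte growth factor gene, made up the 5 largest increases. The 5 largest decreases were Chm, mutated in choroideremia (80.6% to 48.1%, adjusted p = 0.115 by Fisher's exact test), 1810030O07Rik, Dusp9, Yipf6 and Brcc3.

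Set against IgG of the same stage and sex, the second-allele excess was found in the H3K27me3 library and not in IgG. Gpc3 had 88.7% in H3K27me3 and 44.6% in IgG (Fisher's exact test, adjusted p = 3.47e-68). Sh3kbp1, an adaptor of receptor endocytosis, had 88.4% and 52.1%, Cask, a synaptic scaffold kinase gene, 87.6% and 45.9%, Pola1, the catalytic subunit of DNA polymerase alpha, 86.2% and 43.2%, and Eda, a ligand in skin appendage development, 81.8% and 48.5%. These 5 genes have the smallest adjusted p and were chosen after their values were seen. Over 452 X genes the median difference was 25.2 points (interquartile range 10.3 to 36.2), with 402 genes higher in H3K27me3 and 47 lower, against a median of 0 on autosomes. The Fisher test called 213 X genes higher and 0 lower, and on autosomes 183 and 227.

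Per allele, second-allele X reads were enriched, and first-allele X reads lay closer to their IgG level. Relative to autosomal reads, second-allele X reads were 2.71-fold those of IgG E12.5 at E11.5 and 3.18-fold at E12.5. First-allele reads were 1.132-fold and 1.23-fold. Against IgG E13.5, a control added after the data were seen, the second-allele values were 1.83 and 2.14 and the first-allele values 0.788 and 0.855. Whether the first allele lay above or below 1 thus depended on the control. On this scale 1-fold is not the level of unmarked genes. Over autosomal genes the median level of both alleles at E12.5 was -0.54 over IgG E12.5 and -0.41 over IgG E13.5 on the log2 scale. Whether the first-allele X carries the mark is not settled by these values. The IgG libraries themselves differed, with 1.44-fold as many first-allele and 1.48-fold as many second-allele X reads, relative to autosomal reads, at E13.5 as at E12.5.

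Among the X lists, housekeeping genes had the highest share at E11.5 and neural or developmental genes the lowest at both stages. The housekeeping list had medians of 79.4% and 77.8% (percentiles 91.8 and 82.2 of random X sets). Examples were Atp7a, a copper transporter gene (85.5% and 87.5%), and Nono, a nuclear RNA-binding gene (84.1% and 86.9%). The list's median second-allele level was 1.63-fold and 1.78-fold that of IgG E13.5, below the 1.85-fold and 2.21-fold of all X genes. Its first-allele level was 0.506-fold and 0.573-fold, against 0.649-fold and 0.696-fold. The higher share thus did not come with a higher second-allele level. Of 23 members with enough reads at E11.5, the binomial test called 12 toward the second allele and 1, Prps1, toward the first (14 and 1 adjusted over the list alone). At E12.5 it called 16 and 1 of 26 (18 and 1 adjusted over the list alone). Gla and Psmd10 were counted among the second-allele calls at both stages. Both had 100% in every IgG library too, in the male with 6 reads and 1 read. Against IgG E12.5 the Fisher test called 8 of 18 higher (12 adjusted over the list alone), with a median difference of 30.8 points. The list's IgG E12.5 median was itself low, at 42.5% (percentile 1.83 of random X sets), against 49.3% in IgG E13.5, which enlarges this difference.

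Neural or developmental genes had medians of 58.4% over 29 genes and 59.6% over 30, lower than all but 0.145% and 0.25% of random X sets. Dmd, the dystrophin gene, stood at 58.3% and 59.3%, and Il1rapl1, a synaptic receptor gene, at 49.1% and 51.7%. Syn1, a synaptic vesicle gene (84.7% and 86.5%), and Gpc3 lay high. The binomial test called 14 toward the second allele and 3 toward the first at E11.5 (15 and 5 adjusted over the list alone) and 18 and 2 at E12.5 (19 and 4 adjusted over the list alone). Between stages Fgf13 and Gpc4 rose by the Fisher test, 4 genes adjusted over the list alone. Against IgG E12.5, 14 of 23 were called higher (15 adjusted over the list alone).

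The neural or developmental list also had more first-allele reads than other X genes. Over 27 genes with usable reads and a balanced IgG share, the median first-allele level was 1.03-fold that of IgG E13.5 at E11.5 and 1.17-fold at E12.5, against 0.649-fold and 0.696-fold over all 491 such X genes. Their second-allele levels were 2.13-fold and 2.60-fold. With reads pooled over all 30 genes of the list, the second-allele values fell to 1.36-fold and 1.62-fold, below the 1.83-fold and 2.14-fold of all X genes, and the first-allele values were 0.902-fold and 0.985-fold, against 0.788-fold and 0.855-fold. Over IgG E12.5 the list's pooled values were 2.43-fold and 2.89-fold on the second allele and 1.60-fold and 1.75-fold on the first. Whether its pooled first-allele reads lay above IgG thus depended on the control. Against IgG E13.5 it also depended on pooling, since the medians over genes lay above 1 and the pooled values below. This measure was chosen after the shares were seen.

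Escape genes, which stay active on the inactive X of somatic cells, had medians of 65.8% and 64.0% over 9 genes. These lay at percentiles 19.2 and 16.6 of random X sets, so the list's share was not set apart from that of other X genes. Kdm6a and Kdm5c, histone demethylase genes, stood at 63.8% and 65.8% at E11.5 and at 50.3% and 55.6% at E12.5, where IgG had 49.3% and 54.5%, and neither was called at either stage. Car5b (91.4% and 87.5%), Mid1 (82.6% and 79.2%) and Shroom4 were the 3 called by the binomial test at each stage (4 adjusted over the list alone). None of the 9 was called between stages. Against IgG E12.5 the Fisher test called 4 of 8 higher, also 4 adjusted over the list alone. Their median second-allele level was 0.971-fold and 0.713-fold that of IgG E13.5, below the 1.85-fold and 2.21-fold of all X genes. With reads pooled over the 9 genes it was 1.74-fold and 1.90-fold, closer to the 1.83-fold and 2.14-fold of all X genes. Mid1, Shroom4 and Car5b held 2112, 1269 and 641 of the list's 4505 reads at E12.5, so these genes carry the pooled value.

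Around the X inactivation centre, Chic1 (87.0% and 88.8%) and Tsx (81.4% and 82.0%) were called by the binomial test at both stages. The list's medians were 68.4% over 6 genes and 81.2% over 7 (percentiles 31.4 and 84.3 of random X sets). The binomial test called 3 at E11.5 (3 adjusted over the list alone) and 4 at E12.5 (6 adjusted over the list alone). Cdx4, a caudal homeobox gene, stood at 44.9% and 60.0%, and no member was called between stages. Against IgG, 2 of 4 were called higher, and 2 adjusted over the list alone. X-linked germline genes had medians of 68.5% over 15 genes and 73.5% over 18 (percentiles 26.6 and 51.5 of random X sets). The binomial test called 7 of them at E11.5 and 11 at E12.5, the same numbers adjusted over the list alone, including Tex11 (78.1% and 80.6%) and Tktl1, a transketolase-like gene (68.5% and 83.3%). Between stages 0 were called, and 1 adjusted over the list alone. Against IgG, 4 of 11 were called higher (5 adjusted over the list alone). Nxf2 and Luzp4 had 73.7% and 77.6% in IgG E12.5, above their H3K27me3 values of 58.9% and 67.6%. Luzp4 was counted among the binomial calls at both stages and Nxf2 at E12.5. Mageb4 (72.7% in IgG E12.5) and Rhox5 (100% of 5 reads there) were also counted at both stages. The binomial test is set against the autosomal share, so it cannot separate the mark from a skew already present in IgG.

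**Figure D3:**
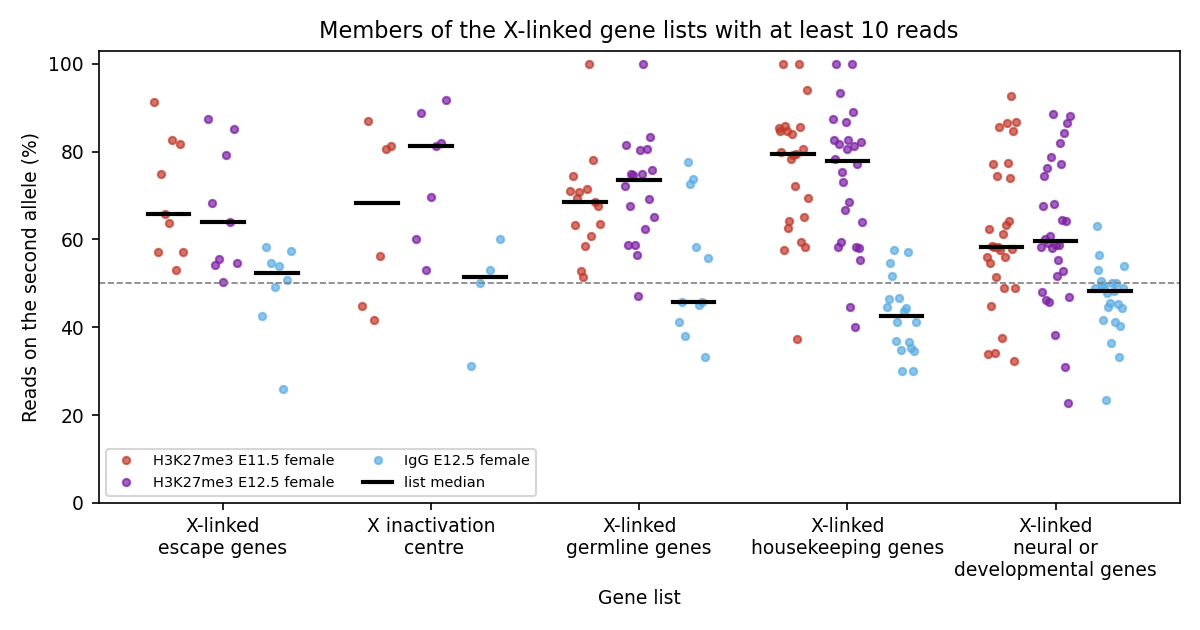
Percent of allelic reads on the second allele for each member of the 5 X-linked lists with at least 10 reads, in both H3K27me3 libraries and IgG E12.5 (points), with the list medians (black bars). Neural or developmental genes have the lowest H3K27me3 medians, 58.4% and 59.6%, and housekeeping genes stand at 79.4% and 77.8%.

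Among the 9 autosomal lists, the highest H3K27me3 levels over IgG were found at Hox genes and developmental regulators, which are known Polycomb targets. Hox genes, the homeobox clusters of body patterning, had a median level of 6.91-fold IgG E12.5 at E11.5 and 7.13-fold at E12.5, and all 30 and 32 measured members were at least doubled. At E12.5 Hoxd3 stood 3.85 above IgG E12.5 and Hoxb3 2.99 on the log2 scale. Developmental regulators had 5.57-fold and 4.16-fold, as in Pax2, a kidney and eye regulator (2.58 on the log2 scale at E12.5), and Nkx2-2, a neural tube regulator (2.65). Somatic gonad markers were at 3.93-fold and 3.49-fold, led at E12.5 by Fst (3.16) and Nr2f2 (3.06), with Wt1 at 1.80. None of 10000 random autosomal sets reached the median of any of these 3 lists. The examples in this paragraph and the next were chosen after their values were seen. Against IgG E13.5 the E12.5 values were 8.59-fold, 6.49-fold and 4.58-fold.

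Germline and pluripotency genes had medians below IgG, as did autosomal genes in general, whose class median at E12.5 was -0.54 on the log2 scale. Scaling to autosomal reads lowers all unmarked genes when others are enriched. Autosomal germline genes had 0.608-fold and 0.526-fold of IgG E12.5 (percentiles 27.7 and 2.65 of random autosomal sets), with 7 of 31 above IgG at E12.5. Ddx4, the germ cell RNA helicase gene, was at -0.99 on the log2 scale at E12.5. Stra8, the gatekeeper of meiotic entry, was above IgG at 1.53, as was Tex101 at 1.76. Pluripotency genes were at 0.583-fold and 0.747-fold (percentiles 30.3 and 61.2), with Pou5f1 at 0.02, and housekeeping genes at 0.483-fold and 0.464-fold (percentiles 2.29 and 0.26). Blood and endothelial markers were at 1.23-fold and 1.22-fold (percentiles 95.4 and 95.8), with Tal1, a blood stem cell regulator, at 2.76. Imprinted genes were at 1.01-fold and 0.916-fold (percentiles 96.2 and 90.0). Genes with oocyte H3K27me3 imprints were at 0.611-fold and 0.552-fold (percentiles 32.0 and 11.2).

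**Figure D4:**
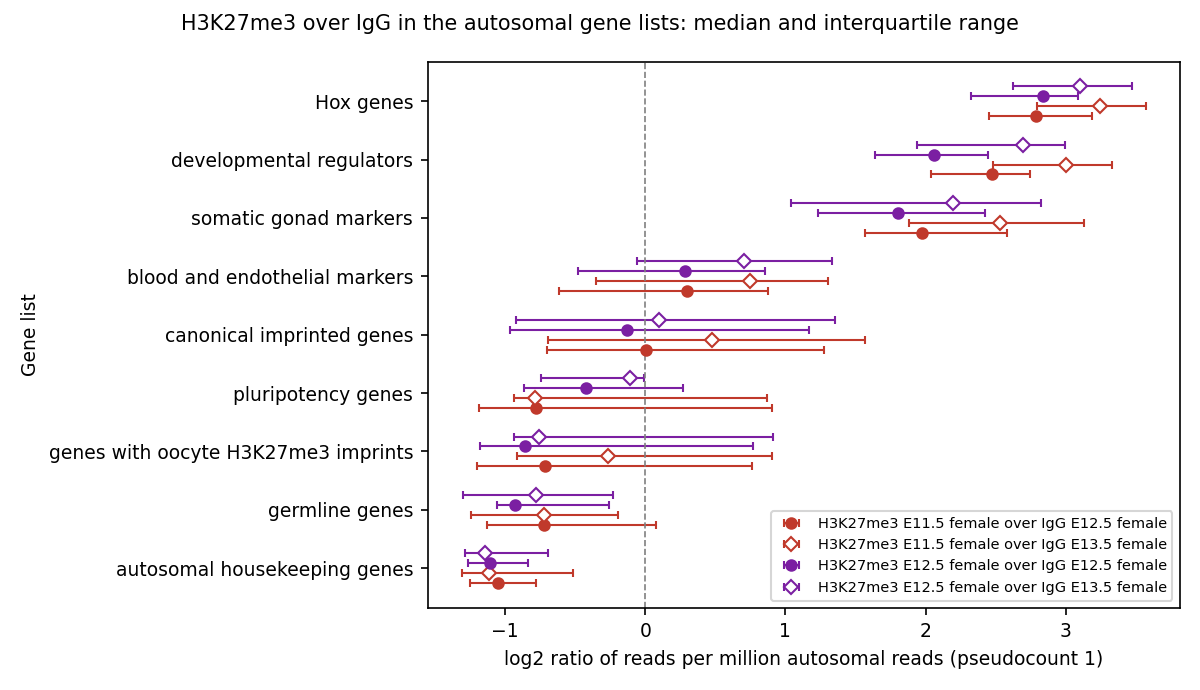
Median log2 ratio of per-gene reads, scaled to autosomal reads with a pseudocount of 1, of each H3K27me3 library over each female IgG library for the 9 autosomal lists, with interquartile ranges as bars. Hox genes lie at 6.91-fold to 9.48-fold, and housekeeping genes lie between 0.454-fold and 0.483-fold.

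The allele shares of the autosomal lists lay near 50%. At E12.5 the medians were 49.6% for Hox genes, 50.3% for developmental regulators, 51.4% for somatic gonad markers, 51.5% for germline genes, 47.9% for pluripotency genes, 50.8% for blood and endothelial markers, 50% for housekeeping genes, 47.6% for genes with oocyte imprints and 51.7% for imprinted genes. At E11.5 the imprinted list had 54.8%, higher than 97.99% of random sets, and the other 8 lists lay between 47.2% and 52.0%. The binomial test called 0 of 32 Hox genes at E11.5 and 2 at E12.5, the same numbers adjusted over the list alone, and 4 developmental regulators above and 1 below of 47 at E11.5 (4 and 1 adjusted over the list alone), and 5 and 1 at E12.5 (4 and 0 adjusted over the list alone). Between stages the Fisher test called 2 members of the autosomal lists, each also called adjusted over the list alone. Mest was lower, and Kit, the stem cell factor receptor gene, rose from 51.7% to 72% (adjusted p = 0.0433 by Fisher's exact test), with 69.4% in IgG E12.5 and 72.8% in IgG E13.5. The pooled share per autosome ran from 49.2% on chromosome 12 to 56.8% on chromosome 17 at E11.5, and chromosome 17 was also the highest in IgG E11.5 male (57.3%) and IgG E13.5 female (57.1%).

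Single imprinted genes, which are expressed from 1 parental copy, departed from equal shares in both H3K27me3 libraries while IgG E13.5 lay near 50%. Grb10, a growth factor receptor adaptor gene, stood at 78.0% and 71.3%, and Gnas, encoding the stimulatory G protein alpha subunit, at 73.4% and 76.0%. Zdbf2 went the other way with 16.1% and 23.0%. In IgG E12.5 they had 56.8%, 61.2% (49.99 to 71.6) and, in Zdbf2, 64.7% of 17 reads. No comparison here separates the parent of origin of an allele from its strain, so which of these underlies the shares was not tested. Grb10, Gnas and Zdbf2 were also among 124 autosomal genes, picked without regard to imprinting, with such one-sided shares at both stages. Below the 20-point threshold, Kcnq1, a potassium channel gene in the cluster of Kcnq1ot1, had 65.3% at both stages (3204 and 5568 reads). Mest, a hydrolase-like gene, fell from 86.9% to 68.8% (Fisher's exact test, adjusted p = 0.0214). These values of Kcnq1 and Mest were singled out after they were seen. Kcnq1 and Gnas overlap antisense transcripts, and reads without strand cannot tell such partners apart. Of the 34 imprinted genes with enough reads, the binomial test called 8 toward the second allele and 3 toward the first at E11.5 (8 and 5 adjusted over the list alone), and 6 and 4 at E12.5 (6 and 4 adjusted over the list alone). Dlk1 and Rtl1 had 96.6% or more on the second allele in both H3K27me3 libraries and 100% in all IgG libraries. Of other list members past the threshold at both stages, En2, a hindbrain homeobox gene, stood at 79.7% and 75% with 60% of 15 reads in IgG E13.5. Foxd3, Slc25a31 and Pgm1 were at 97.8% or more in both H3K27me3 libraries and at 99.1% or more in IgG E13.5, Foxd3 there with 4 reads.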

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

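All tests in this part were chosen after the results were seen. Y chromosome genes, not used in any comparison, had 5 reads in H3K27me3 E11.5 female, 4 in H3K27me3 E12.5 female and 35 in IgG E13.5 female, above the limit of 3 reads that a count of 0 allows, against 9 in the male library. Per 10 to the power of 6 reads these were 2.04, 0.762 and 5.95, against 6.53 in the male library and 1.29 in IgG E12.5 female. In IgG E13.5 female, 30 of these 35 reads lay on genes with a single copy on the Y. The pooled X share of this library was 49.5%, against 6.30% in the male library. The source of its Y reads was not tested. Genes listed at a pair of positions took 0.112% and 0.104% of the H3K27me3 reads at E11.5 and E12.5, above the 0.0686% to 0.0717% of the IgG libraries, with 2482 of the 2745 and 5003 of the 5462 reads on Pakap.

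The first pattern weighed is the second-allele excess on the X in both H3K27me3 libraries. A mapping preference would shift IgG alike, but the median X gene lay 25.2 points above IgG at E12.5. Second-allele X reads, relative to autosomal reads, lay 1.83-fold or more above IgG at both stages and with both female controls, beyond the 1.48-fold between these controls. These values go with H3K27me3 enriched on the second-allele X. That is the X with an intact Xist if the knockout is on the same allele in both sexes. No earlier stage was sampled, so a gain over time was not measured. Somatic cells in the pool cannot be told apart from germ cells as the source of the excess. The mark at somatic gonad markers was 4.58-fold over IgG E13.5 at E12.5, with 2611 reads on Gata4 and 1030 on Wt1. It could lie in germ cells that do not use these genes, or in other somatic cells that the Oct4-eGFP sort is meant to remove. A change with stage in this excess stays untested without the files of the replicates.

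The second pattern is the lower second-allele share of X neural or developmental genes. Weak marking diluted by background as the whole cause is argued against by random X sets matched on second-allele level over IgG E13.5, of which the list's median share lay at the 0.075 percentile or below. With pooled reads the list's second-allele level was below that of all X genes, so dilution at single genes stays open, as for Dmd, whose level with both alleles at E12.5 was -0.035 over IgG E13.5 and 0.976 over IgG E12.5 on the log2 scale. Gene length as the whole cause is argued against by random sets matched on length, of which the list's median lay at the 0.16 percentile or below. Whether H3K27me3 also lies on the first-allele copy of these genes cannot be read from 1-fold, which is not the level of unmarked genes. Their pooled first-allele reads were 0.902-fold to 0.985-fold those of IgG E13.5 and 1.60-fold to 1.75-fold those of IgG E12.5. For X housekeeping genes these values were 0.560-fold to 0.611-fold and 0.621-fold to 0.678-fold. For all X genes they were 0.788-fold to 0.855-fold and 1.132-fold to 1.23-fold. The median over the list's genes was 1.03-fold and 1.17-fold that of IgG E13.5, at percentiles 99.9 and 99.95 of random X sets. These values go with H3K27me3 on the first-allele copy of these genes too. The amount stays open, as no unmarked first-allele level was measured. Gpc3 and Syn1 in this list do not show the lower share.

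The third pattern is 14 X genes with at least 95% of reads on the second allele in IgG E13.5 female. No biological explanation was tested for it. In the male library, whose X is otherwise the first allele, 34 of their 36 reads (94.4%, 81.3 to 99.3) lay on the second, which is consistent with a strain variant or mapping difference at these genes. Only 9 of the 14 had male reads, so the others stay open.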

How the results depend on the processing

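The alternatives with IgG E13.5 as the control, without X genes skewed in IgG E13.5 female, without chromosome 17 and of the autosomal shares were chosen after seeing the data. No paired analysis was possible because each group had 1 library with a file. The second-allele excess on the X in H3K27me3 kept its direction under all alternatives run, and the cause of the shifts was not tested unless stated. With the mean over genes, the X shares were 70.5% (E11.5), 70.3% (E12.5), 5.51% (male) and 51.1% (IgG E13.5, which crossed 50%), the stage change 0.375 and the difference from IgG 23.0 points, and the autosomal shares 52.0%, 51.5%, 51.2%, 51.5% and 51.9%. Pooled reads gave 69.4%, 71.0%, 6.30% (male) and 48.7% (IgG E12.5) on the X, a difference from IgG of 22.3 points, and 51.6%, 50.9%, 50.8%, 51.1% and 51.3% on autosomes. Relative to IgG E12.5 per gene, the X shares were 75.5%, 75.2%, 7.74% (male) and 51.6% (IgG E13.5, which crossed 50%), 8 X genes lay past the threshold on the first-allele side at E12.5, and Nxf2 (35.2%), Luzp4 (40.0%) and Prps1 (50.2%) changed side. Relative to IgG E13.5 per gene, they were 70.7% at E12.5 and 5.54% in the male, the difference was 20.7 points and 7 X genes were called lower. Against that control the first-allele X reads went to 0.788-fold and 0.855-fold, the other side of 1, and the second-allele reads to 1.83-fold and 2.14-fold. The stage change was 1.84 points relative to autosomal medians and 0.191 in 1 Mb bins.

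Counts past the threshold move by construction with the threshold and the number of units tested. In 1 Mb bins they were 54 and 1 (second and first allele, E11.5), 59 and 3 (E12.5), 95 (male, first allele), and 6 and 8 on either side in IgG E12.5 and E13.5. At 10 points, 30 and 36 genes lay on the first-allele side in H3K27me3, and 155 and 128 on either side in IgG. At 30 points these were 206 and 2 (E11.5), 238 and 5 (E12.5), and 12 and 22 (IgG). With at least 5 reads, 13 lay on the first-allele side at E11.5, 91 and 74 on either side in IgG, and the male median was 3.08%. With at least 20 reads, 7 did at E12.5, 217 in the male, 19 and 24 in IgG, and 1 X gene was called lower than IgG. Over genes with a value in all 5 libraries the counts were 188 and 3 (E11.5), 192 and 2 (E12.5), and 18 and 5 (IgG), and the binomial test called 7 toward the first allele at E11.5, and 251 toward the second and 10 toward the first at E12.5. Without X genes skewed in IgG E13.5 female, 0 remained there. Without chromosome 17, 14 autosomal genes were called higher at E12.5 and 18 lower. Of the alternative values of the gene lists, 19 lay within the counting interval of the value reported and 9 outside, and of those of the named genes 35 and 42, besides the 3 that changed side. With random sets of matched coverage, chosen after seeing the data, 4 of 70 list medians lay outside the central 95% of the sets, in place of 6. A shift of 20 points between stages was recovered in 34% of simulated genes, and in 77.3% of those with at least 100 reads.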

Other observations

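All values in this part were chosen after they were seen. Autosomal genes with a balanced share in IgG E13.5 also showed one-sided H3K27me3. Of 10913 autosomal genes with an IgG E13.5 share within 10 points of 50%, 124 lay at least 20 points from 50% on the same side in both H3K27me3 libraries, 66 toward the second allele and 58 toward the first, and 0 lay on opposite sides. When the shares of E12.5 were shuffled among genes 1000 times, a median of 4 and at most 12 genes did so. Balance was required in IgG E13.5 alone. Of the 124 genes, 117 had at least 10 reads in IgG E12.5, and 3 of these lay at least 20 points from 50% on the same side there, among them Fcgr4 with 78.6% of 14 reads. In IgG E11.5 male some also lay that far on the same side, such as Rragd (70.6% of 51 reads) and Rbfa (80% of 15). Gimap5 lay on the other side there, with 25% of 16 reads. The residual strain background of the animals behind each library is not in the labels. Grid1, a glutamate receptor family gene, had 25.9% and 27.6% on the second allele (2931 and 5289 reads), Greb1l, a gene of kidney development, 27.3% and 25.2%, Slc38a1, an amino acid transporter gene, 90.6% and 88.2%, and Pck2, a mitochondrial gluconeogenic enzyme gene, 95.9% and 91.0%.

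Neighbouring genes shared a side in 9 runs (mm10). On chromosome 3 from 108283974 to 108416069, Sort1, Mybphl, Psrc1 and Celsr2 lay toward the first allele. On chromosome 14 from 55478741 to 55550020, Dhrs4, Carmil3 and Pck2 lay toward the second allele, and on chromosome 7 from 26757142 to 26843264, Cyp2b19, Cyp2g1 and Cyp2a5, genes of the cytochrome P450 family, toward the first.

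In autosomal 2 Mb bins with at least 100 reads in each library, the share differed between libraries by over 20 points in 7 of 1092 bins. The median range was 5.10 points. On chromosome 17 from 74 to 76 Mb, which holds Ltbp1, Rasgrp3 and Birc6, the shares were 84.2% and 48.9% in H3K27me3 E11.5 and E12.5, 79.5% in IgG E11.5 male, and 52.0% and 80.4% in IgG E12.5 and E13.5. Another 9 bins had at least 75% on the second allele in all 5 libraries, among them chromosome 2 from 118 to 120 Mb, with 92.7% to 94.3%.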
